A study of Arabidopsis thaliana with 24 samples.

How the data were processed

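Total RNA of source leaves was measured on Agilent Arabidopsis arrays in 1 colour, with 24 arrays in 8 groups of 3: wild type and the lines labelled 35S-STKR1 1, 2 and 5, each in light and in extended dark. Groups and replicate numbers were taken from the sample titles. The genotype tags of lines 2 and 5 name the transgene with the line's number, and were read as line names. Nothing in the labels says whether the 3 samples of a group were separate plants, so the p-values measure only the spread between these samples. The arrays lay on 3 slides of 8. All wild type dark arrays were on slide 3, and all line 1 dark arrays were on slides 1 and 2. Slide and genotype therefore overlap in dark, and for line 1 they cannot be separated within a slide.

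Per the file headers, the deposited intensity values came from scanner G2600D and Feature Extraction 11.5.1.1 with protocol GE1_1105_Oct12, which subtracted background within each array and did not scale between arrays. The authors' series matrix holds log2 values, 1 column per sample, whose making the labels do not describe. Its column medians ran from -0.329 to 0.358. It correlated at 0.9988 or higher per array with values rebuilt as log2 intensity minus the array's 75th percentile and minus each probe's median over the arrays. The matrix was used as an alternative only, and its exact construction stays unknown.

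Each array held 62976 spots, of which 1319 were controls, and 59017 other probes for 30541 loci, designed on the TAIR10 build per the file headers. The processed signal was put on the log2 scale and centred on the array's 75th percentile, spots that Feature Extraction marked as outliers were left out, and spots of a probe were averaged. Probes well above background on every array of at least 1 of the 8 groups were kept (39037 probes, 20415 genes). The share of probes well above background was 59.3% to 65.6% per array. Each gene was represented by its brightest probe. Of 14207 genes with several probes, 9, 12, 31, 21 and 16 had probes that moved in opposite directions by over 1 log2 unit each way, in lines vs wild type in light and in dark, dark vs light in wild type and in lines, and the interaction. In the same order, the probes of 447, 737, 940, 666 and 642 genes were spread over more than 1 log2 unit. 262 probe sequences were shared by several loci. Gene symbols came from the reference of assembly TAIR10.1, used for names only, which held 20144 of the 20415 loci.

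Comparisons were tested with limma 3.58.1 (lmFit on group means, then eBayes) in R 4.3.3, with data.table (version 1.17.8) for reading, and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The contrasts were the mean of the 3 lines and each line against wild type in light and in dark, dark against light in wild type and in the lines, and the interaction of genotype and dark. Differences among the 3 lines were tested with a moderated F test, and genes called in the same direction in all 3 lines were counted. Since the 3 line contrasts share the wild type arrays, the overlap was set against independent lists and against 100 simulations of unchanged lines with shared controls.

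26 gene lists (413 loci, 380 tested) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a contrast, with an estimated correlation and fry beside it. They cover salicylic acid and systemic acquired resistance, pattern-triggered immunity, NLR immune receptors, jasmonate and ethylene defence, SnRK1 starvation targets, SnRK1 subunits, photosynthesis and chlorophyll synthesis, circadian clock, cell wall loosening, cell cycle, cytokinin response, aliphatic and indole glucosinolate synthesis, senescence, endoplasmic reticulum folding, starch and sugar metabolism, abscisic acid, cold and drought, flavonoid and anthocyanin synthesis, flowering time, cytosolic ribosomal proteins, the GeBP family, and markers of guard cells, phloem, xylem, epidermis and trichomes, and meristems and flowers.

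The lists, tests, alternatives and the rule for named genes were set before the data were examined. For lines vs wild type the rule names STKR1, the 10 highest and 10 lowest log2 differences among genes past the threshold in the contrast and in each line in the same direction, and up to 4 members per list with the largest absolute difference among those past the threshold, or up to 2 where none passes. For dark vs light in wild type it names the 8 highest and 8 lowest and up to 4 members per list, for the interaction the 5 highest and 5 lowest, and for differences among lines the 5 smallest p in light and in dark. The report prints a part of these genes.

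The test was tried on simulated data with independent noise and with 67, 67 and 66 genes changed by 1.5, 2 and 4-fold. For lines vs wild type it found 22.4%, 46.3% and 75.8% of them, with 6 false calls among the unchanged ones of the 20415 genes. For 1 line it found 11.9%, 38.8% and 71.2% (10 false), and for the interaction 10.4%, 32.8% and 68.2% (7 false). Among lines it found 13.4%, 46.3% and 71.2% (7 false), and the list test found the 1 changed list of 26. Most of the real comparisons called far more genes, so these shares and false calls need not carry over to them.

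Alternatives were normexp background correction with offset 50, quantile normalization, no filter on dim probes, slide as a block, replicate number as a block, both blocks together, the series matrix, eBayes with trend and robust, only the groups compared, the mean over a gene's probes, a log2 difference of at least 1, each array left out in turn, the line as a random block, an unadjusted p under 0.01 in each line, and, added after seeing the data, leaving out the 4 arrays that stood apart. Splits of the same arrays into other groups were counted for each comparison.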

Results

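Gene expression was measured in mature source leaves, the grown leaves that export sugar, of 4-week-old Arabidopsis thaliana plants. Wild type plants of the Col-0 accession were compared with transgenic plants labelled 35S-STKR1 lines 1, 2 and 5, in which the strong 35S promoter of a plant virus is meant to drive STKR1. STKR1 (AT4G00270) is a DNA-binding protein of the GeBP family, and the series' title names it as a partner of SnRK1, a protein kinase that is active when cells run short of energy. Leaves were taken after 6 h of light or after a dark period extended by 6 h. Each of the 8 combinations of genotype and treatment had 3 arrays, 24 in all, with RNA labelled in 1 colour, and this number of arrays limits the precision. On each array, between 59.3% and 65.6% of the probes were well above background, and 20415 genes were tested. The title names growth, development and immunity as the processes under study.

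On the tested probe of STKR1 (chromosome 4, 117477 to 118468, TAIR10 build per the file headers), the lines labelled 35S-STKR1 did not have a higher signal than the wild type. In light the mean log2 signal was 0.37 ± 0.11 (SD, n = 3) in wild type leaves, and -0.21 ± 0.08, 0.11 ± 0.35 and 0.13 ± 0.05 in the lines labelled 1, 2 and 5. In dark it was -0.18 ± 0.19 in wild type leaves, and -0.86 ± 0.39, -0.56 ± 0.34 and -1.09 ± 0.12 in the same lines. The mean of the lines minus wild type was -0.35 ± 0.16 (SE, adjusted p = 0.0998) in light and -0.66 ± 0.16 (adjusted p = 0.00268) in dark, so the signal fell past the threshold in dark only as far as these 2 tests go. The difference between these 2 values was not past the threshold (log2 interaction -0.31, adjusted p = 0.432). Line by line in dark, lines 1 and 5 were lower (-0.68, adjusted p = 0.0129 and -0.91, adjusted p = 0.00193) and line 2 did not pass (-0.38, adjusted p = 0.109). The call in line 1 ended with only the groups compared (adjusted p = 0.0768) and without wild type dark replicate 2 (adjusted p = 0.0558) or line 1 dark replicate 2 (adjusted p = 0.0653). A second probe of the gene gave -0.45 (adjusted p = 0.033) in light and -0.47 (adjusted p = 0.0164) in dark. The coordinates are those of the gene, and whether either probe lies in the part of the transcript that the transgene carries is not given in the sources used here. The tested probe has no reading frame free of stop codons, so it may lie outside the coding sequence. Because the overexpression that the labels name was not seen in these signals, the plants are called the labelled lines. Every direction given for them rests on the labels.

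The arrays lay mostly apart by treatment along the first principal component (56.2% of the variance), and by wild type against labelled lines along the second (24.3%). 4 arrays stood apart from the other arrays of their group, with a root mean square deviation over 1.5 times the median of 0.399: line 1 dark replicate 3, line 2 light replicate 2, line 2 dark replicate 1 and line 5 light replicate 3. In light, line 5 was spread widely: the log2 signal of PR1 was 3.15, -1.54 and 7.25 in its replicates 1, 2 and 3, and the correlation of replicates 2 and 3 was 0.894.

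**Figure D1:**
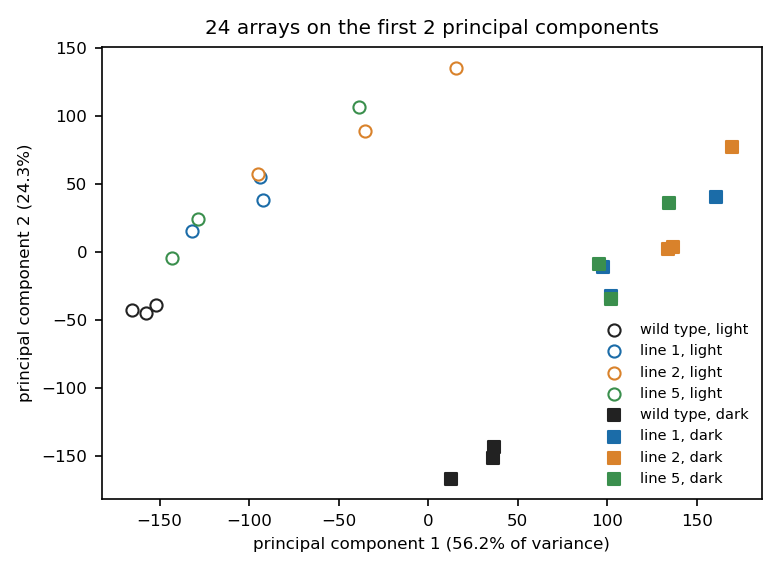
Each point is 1 of the 24 arrays on the first 2 principal components of log2 signal (axes in component units, with 56.2% and 24.3% of the variance); colour gives the genotype and marker the treatment. The arrays taken in light lie to the left of those taken in dark except line 2 light replicate 2, which matches the wild type in dark on the first axis and lies at the opposite end of the second, and line 5 in light is spread along both axes.

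In light, 24 of 27 salicylic acid genes were higher in the labelled lines than in the wild type. The median log2 signal of this list was -0.06 on line 5 light replicate 2, near the -0.66 to -0.27 of the wild type arrays. On the other line arrays in light it was 1.41 to 3.29. PR1, the standard marker gene of salicylic acid signalling, was 10.31 ± 1.13 log2 units (SE, 9 against 3 arrays) higher in the labelled lines (adjusted p = 6.49e-06), with 2 of the 3 wild type arrays above background. Of 18 genes for abscisic acid, cold and drought 12 fell, as did 12 of 15 in the aliphatic glucosinolate pathway, which makes sulfur-rich defence compounds from methionine. All 14 tested folding proteins of the endoplasmic reticulum rose. In total 3190 genes were higher and 3192 lower, and 2907 of these 6382 differed by at least 1 log2 unit. The balance depended on the scaling, with 3711 higher and 3010 lower under quantile normalization and 2953 and 3486 under normexp.

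**Figure D2:**
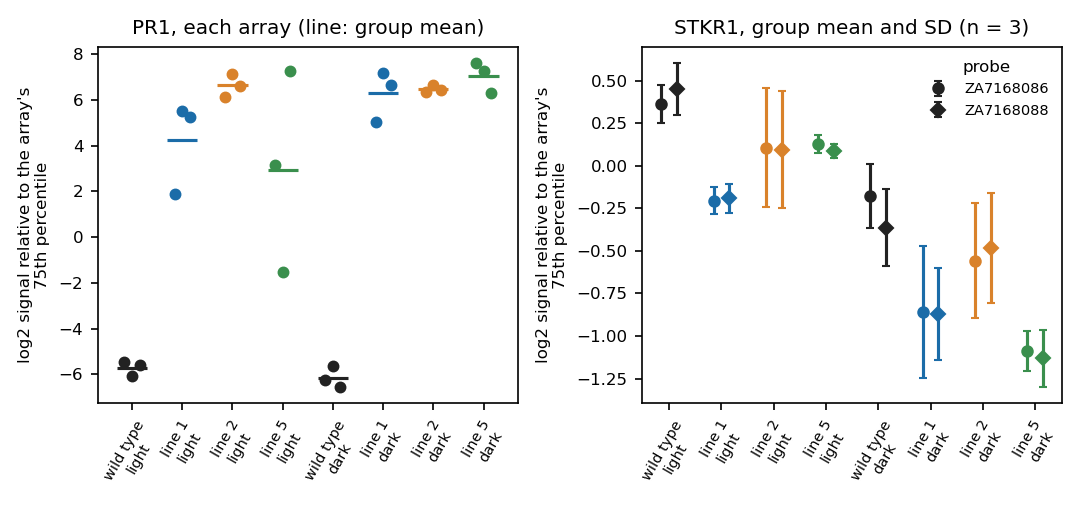
Left, log2 signal of PR1 on each array (points, 3 per group) with the group mean (line); right, group mean and SD (n = 3) of both probes of STKR1, by genotype and treatment. PR1 lies near -6 in the wild type and between -1.54 and 7.6 in the labelled lines, while the group means of STKR1 are not higher in the labelled lines.

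Of the 27 tested genes of the salicylic acid and systemic acquired resistance list, 24 rose and 3 did not pass, with the same 24 adjusted over the list alone (median log2 difference 3.05, camera adjusted p = 5.16e-13). With an estimated correlation neither this list nor any other of the 26 passed camera's test in light (adjusted p = 0.504 or higher, with 1 list at an unadjusted p under 0.05). Fry called 12, but not the same 12 as camera with its preset correlation. It lost the NLR (adjusted p = 0.0708), photosynthesis (0.15) and senescence lists (0.0502). It gained the flavonoid (0.00613), flowering time (0.0246) and phloem lists (0.0331). ALD1, an enzyme of pipecolic acid synthesis, was 5.04 higher, above background on 1 of 3 wild type arrays. UGT76B1, a glucosyltransferase that acts on salicylic acid, was at least 14.1-fold higher on its tested probe, and FMO1, which makes the mobile immune signal N-hydroxypipecolic acid, was at least 15.6-fold higher. Where the tested probe was well above background on no array of a group, such a fold is a lower bound. It sets the mean of the brighter group against, for each dim array, the higher of the probe's own signal and the lowest signal of any probe well above background on that array. The numbers of arrays above background are by gene, and count an array where any of its probes was. The pattern-triggered immunity list, of genes induced when plants sense microbes, had 20 of 28 genes higher and 8 not past the threshold, or 21 higher and 1 lower adjusted over the list alone (median 1.32, camera adjusted p = 5.08e-09). NHL10, a membrane protein induced by microbial patterns, was at least 30.7-fold higher on its brightest probe, and 2.62 log2 units on its other probe. CYP71A13 and CYP71A12, which act in synthesis of the antimicrobial camalexin, were 4.91 and 4.68 higher. Among 18 NLR immune receptors, intracellular sensors of pathogen effectors, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.29, camera adjusted p = 0.0479). The helper receptors ADR1, ADR1-L2 and ADR1-L1 were 1.93, 1.57 and 1.11 higher, while RRS1 was -0.87. With slide as a block this list no longer passed (adjusted p = 0.0576).

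The jasmonate and ethylene defence list went both ways in light, with 9 of 22 genes higher and 2 lower, the same counts adjusted over the list alone (median 0.81, camera adjusted p = 0.0479). With an estimated correlation its adjusted p was 0.509, and those of the senescence, endoplasmic reticulum and ribosomal lists were 0.606, 0.504 and 0.509. TAT3, a jasmonate-induced tyrosine aminotransferase, was 5.43 higher and JAZ10, a repressor of jasmonate signalling, at least 3.09-fold higher, while CORI3, another jasmonate-induced gene, was -5.88. This list did not pass under normexp (adjusted p = 0.118) or quantile normalization (adjusted p = 0.0543). In the senescence list 5 of 13 genes rose, also 5 adjusted over the list alone (median 1.05, camera adjusted p = 0.0112), among them SAG21 (3.62), WRKY6 (2.52) and WRKY75 (at least 6.84-fold). All 14 genes for endoplasmic reticulum folding rose, also adjusted over the list alone (median 1.44, camera adjusted p = 2.9e-08), led by the chaperone BIP3 (2.91) and the disulfide isomerase PDIL1-2 (2.29). 10 of 18 genes for cytosolic ribosomal proteins rose, or 12 adjusted over the list alone (median 0.38, camera adjusted p = 1.37e-05), such as RPL23AA (0.91) and RPS6A (0.75).

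Several metabolic and hormone lists were lower in light by camera's test with its preset correlation. An estimated correlation gave adjusted p of 0.504 for abscisic acid, cold and drought and for aliphatic glucosinolates, 0.606 for starch and sugar metabolism, 0.561 for cytokinin response and 0.772 for photosynthesis. Of 18 genes for abscisic acid, cold and drought, 12 fell, or 13 adjusted over the list alone (median -1.76, camera adjusted p = 1.64e-05). The cold-protective RD29A and COR15A were -2.89 and -2.90, the cold regulator CBF3 -2.16, and KIN1 at least 4.48-fold lower. Of 15 genes for aliphatic glucosinolate synthesis, 12 fell, or 14 adjusted over the list alone (median -1.42, camera adjusted p = 1.79e-06), with CYP79F1 and CYP79F2, the entry enzymes, at -2.06 and -2.14 and the side-chain oxygenase FMO GS-OX1 at -2.60. In starch and sugar metabolism 6 of 17 genes fell and 1 rose, or 10 and 1 adjusted over the list alone (median -0.76, camera adjusted p = 0.0388). Starch branching enzyme SBE2.1 was -1.05 and the starch phosphorylating enzyme SEX1 -0.92, while GPT2, which carries glucose 6-phosphate into plastids, was 5.13 higher and above background on 1 wild type array. For cytokinin response, 4 of 11 genes fell, the same 4 adjusted over the list alone (median -0.74, camera adjusted p = 0.0305), with the response regulators ARR15 (-3.33, above background on 3 of 9 line arrays) and ARR16 (-1.55). This call ended with only the groups compared (adjusted p = 0.064). Photosynthesis and chlorophyll synthesis shifted little: 2 of 34 genes fell, LHCB4.3 (-0.97) and PSBQ2 (-0.80), and none passed in limma's test adjusted over the list alone, with the median at -0.47. Its camera adjusted p of 0.00694 rose to 0.199 under quantile normalization. The lists of markers of other cell types did not pass camera's test in light, while fry called the phloem markers (median -0.27, adjusted p = 0.0331). In light 2 of 9 phloem markers fell, SEOR1 (-1.35) and APL (-0.57), as did 1 of 5 xylem markers, IRX3 (-2.65, above background on 3 of 9 line arrays). The guard cell and epidermis and trichome lists had medians of -0.33 and -0.75, with GC1 at -1.06 (adjusted p = 0.0866) and TRY at -1.12 (adjusted p = 0.29).

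The other lists did not pass camera's test in light. For indole glucosinolate synthesis 3 of 6 genes rose, CYP79B2 (1.85), MYB51 (1.35) and CYP83B1 (0.96), with an adjusted p of 0.188 for the list. Of 21 cell cycle genes 8 rose and 4 fell. The replication helicase subunits MCM2 (1.69) and MCM7 (1.48) and the mitotic cyclin CYCB1;1 (1.95, above background on 1 of 3 wild type arrays) were among those that rose, and the list's median (-0.59) and mean (-0.01) lay below 0 while camera's direction was up (adjusted p = 0.624). SnRK1 starvation targets, genes induced when the kinase is active, went both ways, with 4 of 20 higher and 5 lower (median -0.36, mean 0.09, adjusted p = 0.683). The dark-induced SEN1 was -1.66 and BT2 1.38. Of 6 SnRK1 subunits 1 fell, AKINBETA1 (-0.53, adjusted p for the list 0.911). In the GeBP family STKL1 fell (-1.72) and GPL3 rose (0.35), out of 5 tested genes (adjusted p = 0.624). The circadian clock list had 1 of 21 genes higher, RVE8 (1.27), and 3 lower (adjusted p = 0.957, median 0.00 and mean 0.05 while camera's direction was down). Cell wall loosening had 4 of 20 genes lower and 1 higher (adjusted p = 0.225), with EXPB3 at -2.52 and XTH17 at least 2.85-fold higher. In flavonoid and anthocyanin synthesis 3 of 10 genes fell (adjusted p = 0.0936), including FLS1 (-1.37), and of 11 flowering time genes SPL3 (-1.06) and SPL9 (-0.88) fell (adjusted p = 0.0936). The 2 tested meristem and flower markers moved apart, PI at least 1.75-fold higher (above background on 6 of 9 line arrays) and AG at least 2.28-fold lower (adjusted p = 0.957).

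Outside the lists, the genes with the highest differences in light in all 3 labelled lines included the vacuolar cation exchanger CAX3 (7.69, adjusted p = 4.65e-10), the calmodulin-like CML41 (7.39, adjusted p = 3.12e-10) and the cation/proton exchanger CHX17 (at least 42.2-fold higher). AT2G44240, a gene of unknown function, was at least 290-fold higher. At the other end stood NAS1, an enzyme of metal chelator synthesis (-7.05, adjusted p = 1.78e-06, above background on 3 of 9 line arrays), the thionin THI2.2 (-6.58, 4 of 9 line arrays), the peroxidase gene AT3G32980 (-6.05, 4 of 9 line arrays), TED6 (-5.51, 4 of 9 line arrays) and the cytochrome P450 CYP81D11 (at least 18.9-fold lower).

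These differences were tested with limma, and 12 of the 26 lists passed camera's test, which assumes a preset correlation between the genes of a list. With slide as a block 5556 genes passed. Within slides 1, 2 and 3 the medians were 2.64, 2.91 and 3.83 for salicylic acid and 1.27, 1.5 and 1.74 for endoplasmic reticulum folding. They were -1.63, -1.21 and -1.68 for aliphatic glucosinolates and -1.93, -1.45 and -2.07 for abscisic acid, cold and drought. Each rests on 1 wild type array, set against 4 line arrays on slides 1 and 2 and 1 array of line 1 on slide 3. The count for lines vs wild type in light was 3787, 3339 or 3837 without wild type light replicate 1, 2 or 3, and 3923 with the line as a random block.

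**Figure D3:**
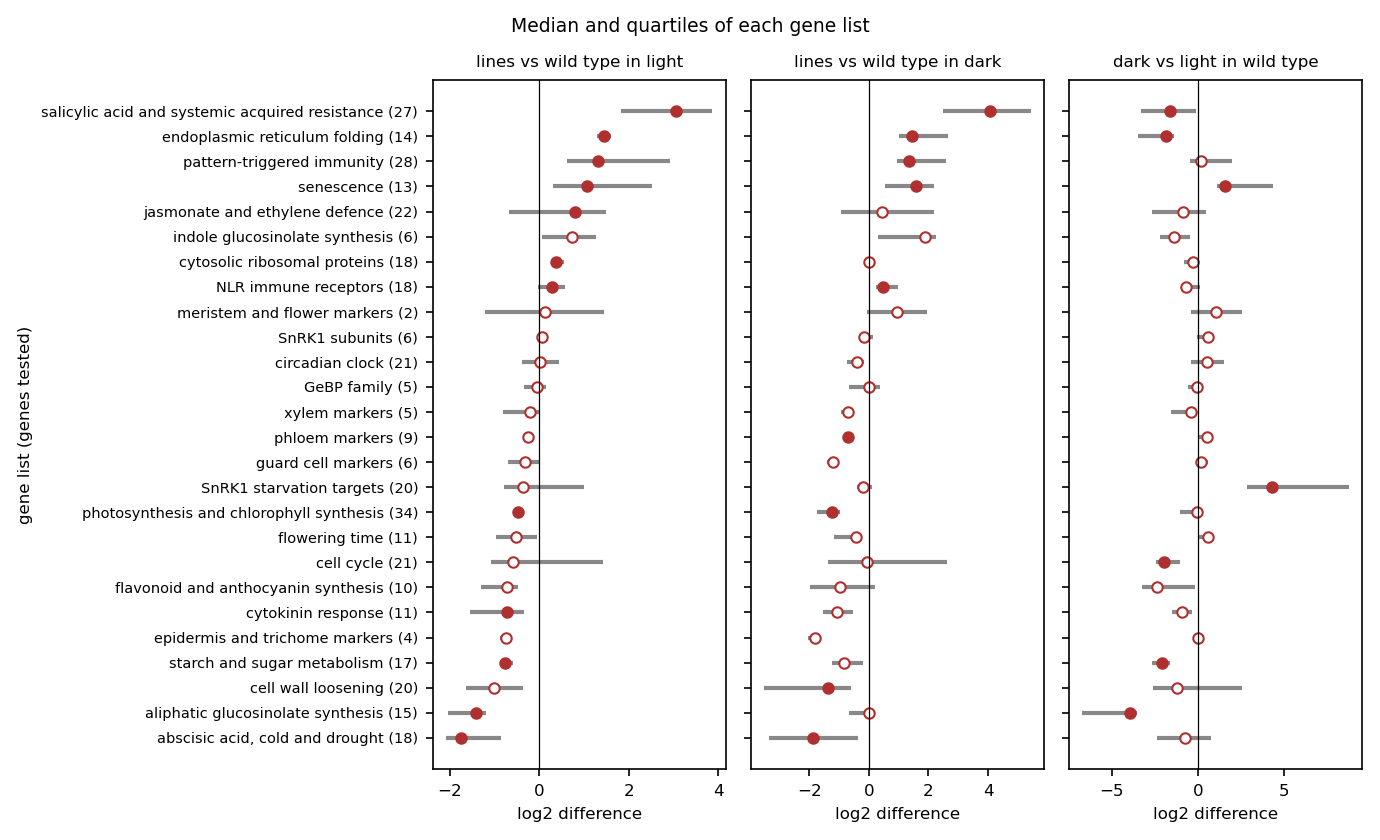
Median log2 difference of each of the 26 fixed gene lists (points, filled where camera's adjusted p is under 0.05) with the quartiles of its members (lines), in the lines vs wild type comparisons in light and in dark and in dark vs light in wild type. The salicylic acid list has its median at 3.05 in light and 4.07 in dark, and the SnRK1 starvation targets at 4.32 in dark vs light in wild type.

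Line by line in light, 2669 genes passed in line 1, 8683 in line 2 and 2311 in line 5, and 815 were higher and 775 lower in all 3. These counts depend on the fit and on single arrays: with only the groups compared line 1 had 6090 and line 5 485, and with each array left out in turn they ran from 1367 to 2116, 4009 to 10037 and 1046 to 3863 for lines 1, 2 and 5. The 1590 genes called in all 3 lines in light became 1026 with only the groups compared, and 791 to 2269 with each array left out. Independent lists of these sizes would share 15.1 and 16.8 genes. Unchanged lines set against the same wild type arrays shared 0 on average in 100 simulations. Lines without changed genes give almost no calls, so this 0 was near fixed in advance. It does not measure how much overlap the shared controls could add. The correlation of the log2 differences across genes was 0.82 for lines 1 and 2, 0.909 for 1 and 5 and 0.871 for 2 and 5, against 0.506, 0.507 and 0.435 in simulation. Their covariances were 1.02, 0.73 and 1.06, against simulated covariances of 0.11, 0.117 and 0.096. The 3 wild type arrays cannot be split into groups of at least 2, so part of the excess over independent lists may come from the shared controls, and genes are not independent replicates.

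In dark, the labelled lines differed from the wild type in salicylic acid and pattern-triggered immunity genes, as in light, and in photosynthesis genes, which were lower. PR1 was 12.75 ± 1.13 log2 units (SE, 9 against 3 arrays) higher (adjusted p = 2.38e-07, above background on 1 of 3 wild type arrays). 31 of 34 genes for photosynthesis and chlorophyll synthesis fell, with a median of -1.24. MCM3, a subunit of the replication helicase, was 4.15 higher, with 2 of 3 wild type arrays above background, while the cell cycle list it belongs to went both ways and the helicase subunit MCM5 did not pass in any line. In total 5389 genes were higher and 6328 lower (4321 and 7016 under normexp), and 5952 of these 11717 differed by at least 1 log2 unit.

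In the salicylic acid list 25 of 27 genes rose in dark, the same 25 adjusted over the list alone (median 4.07, camera adjusted p = 6.27e-13). An estimated correlation ended this and every other list call by camera in dark (adjusted p = 0.504 or higher, with 0 lists at an unadjusted p under 0.05), while fry called 22. DLO1, which degrades salicylic acid, was at least 72.3-fold higher, FMO1 at least 100-fold and ALD1 at least 26.9-fold. The pattern-triggered immunity list had 21 of 28 genes higher and 4 lower, the same counts adjusted over the list alone (median 1.35, camera adjusted p = 8.56e-06), with CYP71A12 at 6.77, CYP71A13 at 6.74 and PAD3, the last enzyme of camalexin synthesis, at 6.08. Of 18 NLR immune receptors 10 rose and 3 fell, or 11 and 3 adjusted over the list alone (median 0.49, camera adjusted p = 0.023), with ADR1 at 2.51 and NRG1.2 at 1.82. For endoplasmic reticulum folding 11 of 14 genes rose, or 12 adjusted over the list alone (median 1.43, camera adjusted p = 8.79e-06), with BIP2 at 2.89, PDIL1-2 at 2.87 and CNX1 at 2.67. Senescence genes rose in 8 of 13 cases, or 10 adjusted over the list alone (median 1.60, camera adjusted p = 0.00378), with WRKY75 at 8.62, above background on 1 of 3 wild type arrays, and WRKY45 at 3.66.

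The fall of photosynthesis genes in dark held for 31 of 34 genes over all genes tested, and 32 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.69e-06, and adjusted p = 0.504 with an estimated correlation). The small subunit of Rubisco RBCS1B was -2.97, and the light-harvesting proteins LHCB2.2, LHCB1.2 and LHCB2.3 were -2.66, -2.68 and -2.30. The list's median was -0.76 under quantile normalization and -0.99 with slide as a block. Within slide 3, which holds all wild type dark arrays, it was -1.24, from 2 arrays of line 2 and 1 of line 5. Markers of other leaf cell types fell beside them: 5 of 6 guard cell markers (median -1.21), all 4 tested epidermis and trichome markers (median -1.82), 8 of 9 phloem markers (median -0.71) and 2 of 5 xylem markers (median -0.69). Examples are the guard cell kinase HT1 (-1.26), the epidermal regulator ATML1 (-1.47), the phloem sugar exporter SWEET11 (-1.13) and the xylem cellulose synthase IRX3 (-3.46, 1 of 9 line arrays). The phloem list passed camera's test (adjusted p = 0.0086), and those of guard cells, epidermis and xylem did not (adjusted p = 0.106, 0.173 and 0.237). Without the 4 arrays that stood apart, chosen after seeing the data, the median of the photosynthesis list was -0.98.

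Abscisic acid, cold and drought genes fell in 11 of 18 cases and rose in 1, the same counts adjusted over the list alone (median -1.86, camera adjusted p = 0.000749, and adjusted p = 0.504 with an estimated correlation). COR15A was -5.19 on its brightest probe, above background on 1 of 9 line arrays, and 0.08 on its other probe, RD29A was -4.57 and COR15B -4.00, while HAI1, a phosphatase induced by abscisic acid, was 4.76 higher, above background on 1 of 3 wild type arrays. Of 20 genes for cell wall loosening 12 fell, also 12 adjusted over the list alone (median -1.37, camera adjusted p = 0.0242, and adjusted p = 0.504 with an estimated correlation), such as XTH15 (-5.29) and EXPA5 (-3.96, above background on 1 of 9 line arrays). The remaining lists did not pass camera's test in dark, but with slide as a block the cell cycle list (adjusted p = 0.0347) and the jasmonate and ethylene list (adjusted p = 0.0349) did. For starch and sugar metabolism 10 of 17 genes fell and 1 rose (adjusted p = 0.0909), with the beta-amylase BAM3 at -1.70 and GPT2 at 6.52 (1 of 3 wild type arrays above background). In indole glucosinolate synthesis 4 of 6 genes rose and 1 fell (adjusted p = 0.0821), with CYP79B2 at 4.64 and the regulator MYB34 at least 6.74-fold lower. Aliphatic glucosinolate genes had 3 of 15 lower and 1 higher (adjusted p = 0.655, median 0.01 and mean -0.24), with the regulator MYB28 at -2.50 (5 of 9 line arrays above background) and the sulfotransferase SOT17 at 3.01. Of 21 cell cycle genes 9 rose and 6 fell (adjusted p = 0.0733, median -0.05 and mean 0.61), with MCM2 at least 10.5-fold and CYCB1;1 at least 4.29-fold higher. SnRK1 starvation targets had 2 of 20 higher and 1 lower (adjusted p = 0.757), and cytosolic ribosomal proteins 2 of 18 each way (adjusted p = 0.609).

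Further from the lists, LAS1, a sterol cyclase, was at least 131-fold higher in dark and the berberine bridge enzyme-like gene AT1G26390 at least 130-fold. The lipid-transfer protein genes AT3G22600 and AT3G22580 were at least 485-fold and at least 99.2-fold higher. CYP81D11 was at least 173-fold lower, AT3G43850, a gene of unknown function, at least 58.9-fold lower on its tested probe, and CORI3 -6.22 (7 of 9 line arrays).

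Adding slide as a block left 7417 genes in dark (3744 higher and 3673 lower). 9 of 26 lists passed camera's test. Line by line, 8052, 11070 and 7621 genes passed in lines 1, 2 and 5, and 3171 were higher and 2622 lower in all 3. With each array left out in turn these counts ran from 4635 to 8034, 7537 to 10383 and 4172 to 7921 for lines 1, 2 and 5, and from 3620 to 5790 in all 3. The counts in all 3 stood against 189.8 and 216.1 for independent lists and 0 in simulation, a value near fixed in advance, as in light. The correlations across genes were 0.939, 0.947 and 0.922 for lines 1 and 2, 1 and 5, and 2 and 5, against 0.462, 0.474 and 0.451 in simulation, and the covariances 1.96, 1.64 and 1.91, against 0.106, 0.103 and 0.095. Part of this excess may come from the shared controls. In that fit with a slide block line 1 had 2515 genes, line 5 had 3799 and all 3 lines shared 2110. No line 1 dark array shared a slide with the wild type dark arrays. The 8052 calls of line 1, and the genes called in all 3 lines, therefore cannot be told apart from a slide difference. A slide block sets line 1 against the wild type in dark only through other groups.

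Across genes, the differences of the labelled lines from the wild type in light and in dark had a correlation of 0.791. Both comparisons called 2201 genes higher and 2267 lower, against 842.1 and 989.4 for independent lists, and 130 genes were called in opposite directions. These comparisons share no arrays.

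In wild type leaves, the extended dark period set off the starvation programme. Of 20 SnRK1 starvation targets 19 rose, with a median of 4.32. IVD and BCAT2, which break down branched-chain amino acids, were at least 652-fold and at least 1720-fold higher. PRODH1, which degrades proline, was 8.81 ± 0.50 higher (SE, 3 against 3 arrays, adjusted p = 2.53e-10) and SEN1 8.93 ± 0.32. All 15 aliphatic glucosinolate genes fell, as did 13 of 17 genes for starch and sugar metabolism. In total 5307 genes were higher and 6397 lower in dark, and 7675 of these 11704 differed by at least 1 log2 unit. Under normexp the balance turned to 6255 higher and 5123 lower.

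The starvation list had 19 genes higher over all genes tested and adjusted over the list alone (camera adjusted p = 6.06e-13), and its call held with an estimated correlation (adjusted p = 0.011). Of 6 SnRK1 subunits 3 rose and 1 fell (adjusted p for the list 0.289), with AKINBETA1 at 4.41 and the catalytic subunit KIN10 at 1.00. Senescence genes rose in 8 of 13 cases, also 8 adjusted over the list alone (median 1.59, camera adjusted p = 0.0101 and adjusted p = 0.819 with an estimated correlation), including the NAC regulators ORE1 (8.98, above background on 1 of 3 arrays in light) and NAP (5.34). All 15 aliphatic glucosinolate genes fell, also adjusted over the list alone (median -3.91, camera adjusted p = 5.11e-09 and adjusted p = 0.219 with an estimated correlation), with CYP79F2 at -7.31 and CYP79F1 at -6.99. For starch and sugar metabolism 13 genes fell, also 13 adjusted over the list alone (median -2.06, camera adjusted p = 8.73e-05 and adjusted p = 0.6 with an estimated correlation), among them the glucan phosphorylase PHS2 (-4.83), the ADP-glucose pyrophosphorylase subunit APS1 (-4.32) and DPE2 (-4.11). Of 14 genes for endoplasmic reticulum folding 12 fell, also 12 adjusted over the list alone (median -1.86, camera adjusted p = 0.00182 and adjusted p = 0.819 with an estimated correlation), with BIP2 at -3.77 and CNX1 at -3.75. Of 21 cell cycle genes 14 fell and 1 rose, the same counts adjusted over the list alone (median -1.95, camera adjusted p = 0.00261 and adjusted p = 0.776 with an estimated correlation), with MCM6 at -2.96 and MCM2 at least 5.97-fold lower. The salicylic acid list had 14 of 27 genes lower and 2 higher, also adjusted over the list alone (median -1.60, camera adjusted p = 0.0284 and adjusted p = 0.844 with an estimated correlation), with WRKY54 at -6.90 and ACD6 at -5.25. This call ended with slide as a block (adjusted p = 0.0505).

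Of 34 photosynthesis genes 8 were lower and 1 higher in wild type dark leaves (adjusted p for the list 0.535, median -0.02 and mean -0.71). Under quantile normalization this list passed, lower in dark (median -0.44, adjusted p = 0.0364). The protochlorophyllide reductase PORC was -4.96, the early light-induced ELIP1 at least 29.4-fold lower and RBCS1B -3.39. In the circadian clock list 9 of 21 genes rose and 5 fell (adjusted p = 0.301), with RVE1 at 4.01 and ELF4 at -3.43. In cell wall loosening 6 of 20 genes rose and 5 fell (adjusted p = 0.62, median -1.19 while the mean was 0.19 and camera's direction up), with XTH22 at 7.78 and EXPB1 at least 47.8-fold lower. The jasmonate and ethylene list had 8 of 22 lower and 3 higher (adjusted p = 0.447), with AOC2 at -4.85, LOX2 at -4.05 and JAZ10 at least 19.2-fold higher. In flavonoid and anthocyanin synthesis 7 of 10 genes fell and 1 rose (adjusted p = 0.107), with FLS1 at least 32.8-fold lower. The genes with the highest and lowest differences included PHI-1, a phosphate-responsive gene (at least 1250-fold higher), MIOX2 (at least 722-fold higher), XTH31 (at least 925-fold lower) and NAS1 (at least 89.9-fold lower). Among markers of other cell types, 5 of 9 phloem markers rose and 1 fell, and 2 of 6 guard cell markers rose (adjusted p for the lists 0.268 and 0.552).

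For dark vs light in wild type 7 of the 26 lists passed camera's test, and 10583 genes passed with slide as a block. Within slide 3, the only slide with wild type arrays of both treatments, the medians were 4.47 for starvation targets, -4.05 for aliphatic glucosinolates, -2.12 for starch and sugar metabolism and -1.33 for the salicylic acid list. They set all 3 wild type dark arrays against 1 wild type light array.

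In the labelled lines the extended dark period also raised the starvation targets and lowered the aliphatic glucosinolate genes. In the mean of the 3 lines 19 of 20 SnRK1 starvation targets rose and 1 fell (median 4.76, camera adjusted p = 1.76e-11 and adjusted p = 0.0188 with an estimated correlation). All 15 aliphatic glucosinolate genes fell (median -4.18), 15 of 17 for starch and sugar metabolism fell (median -2.14) and 12 of 13 senescence genes rose (median 2.23), with camera adjusted p of 3e-06, 7.68e-05 and 0.000311. With an estimated correlation these 3 and the other 4 lists that passed lost their calls (adjusted p between 0.478 and 0.862). Photosynthesis genes fell in 23 of 34 cases (median -1.07, camera adjusted p = 0.00143) and genes for cytosolic ribosomal proteins in 17 of 18 (median -0.67, camera adjusted p = 0.000352). Endoplasmic reticulum folding fell in 12 of 14 cases and rose in 1 (camera adjusted p = 0.000986), and cell cycle genes fell in 16 of 21 and rose in 1 (camera adjusted p = 0.0377), a call that ended under normexp (adjusted p = 0.0553) and quantile normalization (adjusted p = 0.0635). In total 7144 genes were higher and 8121 lower in dark, and 7974 of these 15265 differed by at least 1 log2 unit. The balance turned to 7696 higher and 7055 lower under normexp, and to 7657 and 7503 under quantile normalization. The dark responses of wild type and labelled lines correlated at 0.854 across genes, with 4716 genes higher and 5578 lower in both, against 1857.1 and 2544.7 for independent lists, and 122 called in opposite directions. Within slides 1, 2 and 3 the starvation targets had medians of 4.72, 4.81 and 4.36.

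The test of the difference between these responses, the interaction of genotype and dark, called 973 genes with a higher and 668 with a lower response to dark in the labelled lines than in the wild type. With each array left out in turn these 1641 calls ran from 747 (without wild type light replicate 2) to 2493 (without line 5 light replicate 3). LURP1, a defence gene, had a log2 interaction of 6.45 ± 0.66 (SE, adjusted p = 2.68e-05) on its brightest probe and 0.83 on its other probe. BGLU46 and CYP82C2 had interactions of 6.27 and 6.08, but neither was above background on any wild type array in dark, so these sizes are not exact. XTH16, a cell wall enzyme, was at -5.39 (adjusted p = 0.0235) and PHI-1 at -5.17 (adjusted p = 0.0134). PHI-1 was above background on 0 of 3 wild type arrays in light and on 1, 3 and 1 of 3 in lines 1, 2 and 5 in light, so its interaction is partly set by the floor. The interaction of NAS1 (6.93) rests on the light arrays, since it was above background only on the 3 wild type and 3 of 9 line arrays in light. No list of the interaction passed camera's test with an estimated correlation (lowest adjusted p 0.873, 0 at an unadjusted p under 0.05), and fry called 0, with an adjusted p of 0.0659 or higher. With the preset correlation 6 did. Among them salicylic acid genes had 5 of 27 higher, or 8 adjusted over the list alone (median 1.52, camera adjusted p = 0.000899), and aliphatic glucosinolate genes 5 of 15 higher, or 8 higher and 1 lower adjusted over the list alone (median 1.16, camera adjusted p = 0.000126). Cell cycle genes had 5 of 21 higher, or 7 adjusted over the list alone (median 0.40, camera adjusted p = 0.00249). Photosynthesis (median -0.66), cytosolic ribosomal protein (median -0.41) and phloem genes (median -0.39) shifted lower, with 1 of 34, 1 of 18 and 2 of 9 genes past the threshold and camera adjusted p of 0.000126, 0.00104 and 0.0428. Guard cell markers, set beside these, had a median of -0.93 (adjusted p = 0.187). Under normexp the salicylic acid, cell cycle and phloem lists did not pass (adjusted p = 0.0949, 0.162 and 0.0949). The number of genes was 941 with slide as a block, and 579 higher against 700 lower under normexp, where the share of higher calls went from 59.3% to 45.3%.

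Among the 3 labelled lines 183 genes differed in light and 252 in dark past the threshold of a moderated F test. These counts hang on single arrays: with each array left out in turn they ran from 11 (without line 2 light replicate 2) to 2228 (without line 5 light replicate 3) in light, and from 109 (without line 2 dark replicate 1) to 552 (without line 1 dark replicate 3) in dark. MRD1 had a mean log2 signal of 1.11 in wild type, 1.2 in line 1 and 1.05 in line 2, and -7.88 in line 5 in light (adjusted p = 7.23e-11, n = 3 per group in limma's test), with -6.75 in line 5 in dark. AT5G03090, whose closest protein match is MRD1 per the array's annotation, was also lower in line 5 (-3.52 in light against -1.13 in line 1). AT4G29780, a gene of unknown function, was low in line 2 alone among the 4 genotypes (-7.94 in light and -8.28 in dark). QQS, a gene known to affect starch content, was at 0.28 in line 1, -7.00 in line 2 and -6.70 in line 5 in light, with the wild type at -3.64 ± 1.31 (SD). A slide block left 108 genes in light and 105 in dark.

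**Figure D4:**
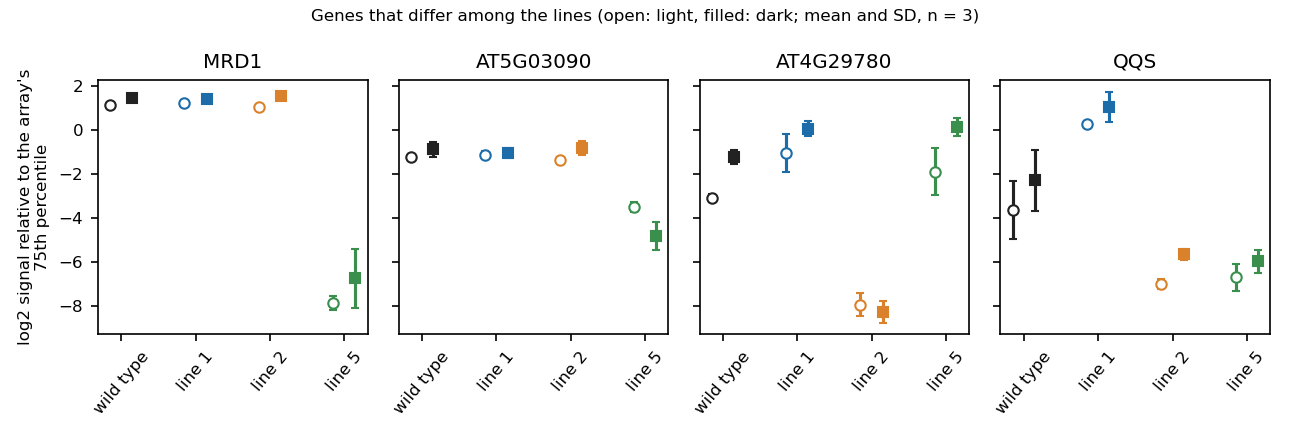
Group mean and SD (n = 3) of the log2 signal of MRD1, AT5G03090, AT4G29780 and QQS by genotype, with open symbols for light and filled symbols for dark. MRD1 is low in line 5 alone and AT4G29780 in line 2 alone, in light and in dark.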

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

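All tests of explanations in this part were chosen after the results were seen, and those for the genes far lower in the labelled lines were also reworked after their first values were known; the splits of the samples were planned. The results below came up because effects differed between groups: the response to dark between wild type and labelled lines (1641 genes past the threshold), and the signal among the 3 labelled lines (183 genes in light and 252 in dark).

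The rule for named genes picked, for the interaction, NAS1 (6.93), LURP1 (6.45), BGLU46 (6.27), CYP82C2 (6.08) and AT2G40390 (5.85) on the higher side, and AT3G43850 (-8.08), AT2G41990 (-6.23), XTH16 (-5.39), PHI-1 (-5.17) and AT3G21330 (-4.93) on the lower. Only LURP1 and XTH16 were above background on every array. Each of the other 8 was so on no array of at least 1 of the 8 groups, which leaves its interaction without an exact size or rank. The smallest adjusted p among lines in light were those of MRD1 (7.23e-11), AT4G29780 (1.75e-07), QQS (2.44e-06), AT5G03090 (0.000146) and AT3G10680 (0.00282). In dark they were MRD1 (3.68e-10), AT4G29780 (2.41e-09), AT5G03090 (3.15e-08), QQS (3.46e-06) and AT3G29140 (7.17e-05), each with n = 3 per line in limma's F test.

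Splitting the same arrays into other groups asked whether chance can be excluded, and each count of splits includes the real one. For lines vs wild type in light 1 of 100 splits gave as many genes (highest other 4189 against 6382). In dark it was 1 of 100 (2698 against 11717), and for dark vs light in the lines 1 of 100 (7782 against 15265). For genes called in all 3 lines it was 1 of 100 in light (19 against 1590) and in dark (8 against 5793). For the interaction 2 of 100 splits gave as many, and the other one gave more (1958 against 1641). The other splits of all these comparisons mix genotypes or treatments within a group, which widens the spread there and lowers their counts. Apart from the interaction, no other split drawn reached the real count, but the splits cannot exclude chance for any of these counts. Chance cannot be excluded for the number of genes that differed among lines in light (11 of 100, highest other 6630 against 183). Nor can it in dark (7 of 100, 1243 against 252), and other splits gave several times the real count in both. That count does not weigh single genes such as MRD1 and AT4G29780, each low in a single line in light and in dark. For the numbers of gene lists chance cannot be excluded in light (10 of 100, 14 against 12) or dark (33 of 100, 14 against 9). The same holds for dark vs light in lines (59 of 100, 13 against 8) and the interaction (59 of 100, 20 against 6). For each single line in light and in dark and for dark vs light in wild type the 10 splits are too few: the real counts were 2669, 8683, 2311, 8052, 11070, 7621 and 11704, with at most 1 gene in any other split, and 9 of 10 splits gave as many lists in wild type (10 against 7).

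150 genes were lower by at least 2 log2 units in each of the 3 lines in light and in dark. A mismatch that spares another probe of the gene would act in light and in dark alike. It was argued against for the genes with several probes. Among these, 3 of 244 probes (1.2%) and 0 of 104 genes had another probe near the wild type in light and in dark together. A sequence difference under all probes of a gene would not show in this count, and genes with a single probe were not covered. The count leaves out genes whose probes part in 1 treatment, such as COR15A, whose other probe was at 0.08 in dark. A single region was argued against, with 10% of the genes in the fullest window of 5 Mb. 54 of the genes had another of a different description among the 5 nearest tested genes on either side, in 20 clusters. The highest in 1000 random sets was 26. Only identical descriptions were left out, so neighbours of a gene family such as CYP705A20, CYP705A21 and CYP705A22 were counted. The count therefore cannot tell such families from regions that differ. The median number of array loci within 0.5 Mb was 263, below the 271 to 291 of random sets. The 282 far higher genes also clustered (69, highest random 59). Small regions that differ between the lines and the wild type, by sequence or chromatin, and a position in gene-poor regions may therefore lie behind part of the pattern, and both stay open.

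31 of 34 photosynthesis genes were lower in the lines in dark. A slide difference was argued against for lines 2 and 5 by the median within slide 3 (-1.24). That slide holds 2 dark arrays of line 2, 1 of line 5 and none of line 1, so it does not cover line 1. With slide as a block the median was -0.99. The scaling of the arrays was argued against by the list's highest median under normexp or quantile (-0.76). A lower share of mesophyll cells would raise the markers of other cell types, but these fell too (median -0.98, 19 of 24 lower). Such markers can also change within their cells, so they cannot settle the share of mesophyll cells. A biological difference between genotypes in dark is consistent with these values, as a hypothesis found and tested on the same data.

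The STKR1 signal was not higher in the lines. Arrays labelled as lines that hold wild type RNA were argued against by 1590 genes called in all 3 lines in light. Of the 2 probes, 1 has a reading frame free of stop codons, and it is not the tested probe on which the STKR1 values rest, so a position of the probes outside the transgene's transcript cannot be told apart from a lack of overexpression, with no transgene sequence to place them on. No biological explanation was tested.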

How the results depend on the processing

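All alternatives were planned except leaving out the 4 arrays that stood apart, which was chosen after seeing the data. Of 327 values of named genes 212 kept direction and side of the threshold in all settings, and 7044 of 7543 checks came out the same; for the values below the cause was not tested. Under normexp 305 genes differed among lines in light, STKR1 in line 1 in light was -0.54 (adjusted p = 0.0476), and AG in dark vs light in wild type changed sign (0.10, adjusted p = 0.604). Normexp moved the median of all genes to -0.157 for lines vs wild type in dark and 0.114 for dark vs light in wild type, and the share of higher calls to 38.1% and 55%. STKR1 in line 1 in light was -0.61 (adjusted p = 0.0489) under quantile normalization and -0.61 (adjusted p = 0.0412) with the mean of probes. Without a filter the interaction had 1046 genes and 15 lists passed in dark. With slide as a block the counts were 7417 in dark, 2515 for line 1 and 3799 for line 5 in dark, 941 for the interaction, 108 and 105 among lines in light and dark, and 2110 in all 3 lines in dark. With only the groups compared, line 1 in light had 6090 genes, line 5 485, all 3 lines 1026, and 5 and 13 genes differed among lines in light and dark, with STKR1 in line 1 at -0.57 (adjusted p = 0.0115) in light and -0.68 (adjusted p = 0.0768) in dark. With the line as a random block 3923 genes passed in light.

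The replicate numbers are not pairs by the labels. As a block check of pairing, residuals of arrays with the same number had a mean correlation of -0.008 (33 of 84 pairs over 0.1), and 7 of 24 arrays were closest to their own number. With replicate as a block 6102 genes passed in light, 11550 in dark, 11546 in dark vs light in wild type and 1415 in the interaction. With replicate and slide as blocks together the counts were 3703 in dark, 4641 for line 2 and 1403 for line 5 in light, 598 for line 1 and 2799 for line 5 in dark, 669 for the interaction, 1017 and 551 in all 3 lines in light and dark, and 11 among lines in light, and STKR1 in line 1 in dark was -0.93 (adjusted p = 0.167). The count of lines vs wild type in light was 4558 in that fit, so the order of light and dark turned, in all 3 lines as well. In dark the calls of the senescence (median 0.61, adjusted p = 0.113), NLR (0.35, adjusted p = 0.13) and cell wall loosening lists (-1.21, adjusted p = 0.0564) ended, and those of the jasmonate and ethylene (adjusted p = 0.0474), cell cycle (adjusted p = 0.00614) and indole glucosinolate lists (adjusted p = 0.0474) were gained. Also ended were the calls of the salicylic acid (0.92, adjusted p = 0.0501) and phloem lists (-0.28, adjusted p = 0.0513) in the interaction, of the NLR list in light (adjusted p = 0.0995) and of the salicylic acid list in dark vs light in wild type (-0.94, adjusted p = 0.237). Gained were photosynthesis (-0.66, adjusted p = 0.0496) and pattern-triggered immunity (1.12, adjusted p = 0.0369) in dark vs light in wild type, and the latter in the lines (0.70, adjusted p = 0.0274).

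Some other list calls changed. In light the NLR and the jasmonate and ethylene lists did not pass with only the groups compared (adjusted p = 0.0653 each), the series matrix (adjusted p = 0.0613 and 0.0532) or the mean of probes (adjusted p = 0.0541 each), nor did the NLR list without the 4 arrays that stood apart (adjusted p = 0.0578). The cytokinin list did not pass in light (adjusted p = 0.064) and passed in dark (adjusted p = 0.0317) with only the groups compared, and passed in dark without the 4 arrays, as did the cell cycle list (adjusted p = 0.0427 each). Flavonoid synthesis passed in light without a filter (adjusted p = 0.0195) and without the 4 arrays (adjusted p = 0.0374). Under normexp the jasmonate and ethylene (adjusted p = 0.026) and indole glucosinolate lists (adjusted p = 0.0148) passed in dark, and the latter in the interaction (adjusted p = 0.0363). Ribosomal proteins passed in dark vs light in wild type under normexp (adjusted p = 0.042) and, with photosynthesis, under quantile normalization (adjusted p = 0.0364 each). The phloem list of the interaction did not pass under quantile normalization (adjusted p = 0.0812), with the mean of probes (adjusted p = 0.0571) or without the 4 arrays (adjusted p = 0.0813), where cell wall loosening passed (adjusted p = 0.0224). Pattern-triggered immunity then passed in dark vs light in lines (adjusted p = 0.0373).

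With a log2 difference of at least 1 the counts were 2907 and 5952 for lines vs wild type in light and dark, 1659, 5057 and 1371 for lines 1, 2 and 5 in light, 4715, 6764 and 4273 in dark, 7675 and 7974 for dark vs light in wild type and in lines, 984 for the interaction, and 966 and 3236 in all 3 lines, by fewer genes counted. STKR1 in dark was under that size (-0.66, and -0.68 and -0.91 in lines 1 and 5). With an estimated correlation camera passed 0, 0, 1, 1 and 0 lists (in light, dark, dark vs light in wild type and in lines, interaction; 1, 0, 2, 2 and 0 at an unadjusted p under 0.05), and fry 22, 14, 20 and 0 in the last 4. Without the 4 arrays that stood apart line 1 in light had 4849 genes, the interaction 2899, and 415 and 457 differed among lines in light and dark. STKR1 was then -0.43 (adjusted p = 0.00712) in light, -0.57 and -0.46 in lines 1 and 2 in light, and -0.57 in line 2 in dark.

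With each array left out in turn, which leaves 2 in its group, the counts ranged from 3339 to 7686 for lines vs wild type in light (3787, 3339 and 3837 without wild type light 1, 2 and 3) and from 8558 to 11860 in dark. The comparison line 1 vs wild type in light had 1367 to 2116 (1550, 1439 and 1693 without wild type light 1, 2 and 3, 1367 and 1480 without line 1 light 2 and 3), line 2 4009 (without line 2 light 2) to 10037, and line 5 vs wild type in light 1046 (without line 5 light 3) to 3863 (without line 5 light 2), with 1254 and 1153 without wild type light 1 and 2. The count for line 1 vs wild type in dark was 4635 (without line 1 dark 3) to 8034, with 5311 without wild type dark 1, line 2 7537 to 10383, and line 5 4172 (without line 5 dark 1) to 7921. Dark vs light gave 10545 to 10806 in wild type and 14850 to 15603 in lines. The genotype by dark interaction had 747 to 2493: 793, 747 and 1050 without wild type light 1, 2 and 3, 799 and 989 without wild type dark 1 and 2, and 2493 without line 5 light 3. Genes called in all 3 lines in light numbered 791 to 2269 (870, 791 and 1035 without wild type light 1, 2 and 3, 1027 without line 1 light 2, 847 without line 5 light 3), and 3620 (without line 5 dark 1) to 5790 for those called in all 3 lines in dark, with 3770 without wild type dark 1. The count of differences among lines in light was 11 to 2228 (74, 111 and 100 without line 1 light 1, 2 and 3, 882, 11 and 100 without line 2 light 1, 2 and 3, 121 and 2228 without line 5 light 2 and 3) and of differences among lines in dark 109 to 552 (552 without line 1 dark 3, 109 and 165 without line 2 dark 1 and 3, 136 and 114 without line 5 dark 1 and 2). Lists past the threshold numbered 9 to 13 in light, 8 to 10 in dark, 6 to 7 and 7 to 9 in dark vs light in wild type and lines, and 5 to 6 in the interaction. The value of STKR1, lines vs wild type in light, ranged from -0.42 (without line 2 light 2, adjusted p = 0.0464) to -0.29, and in dark from -0.74 to -0.56. In lines 1, 2 and 5 it ranged from -0.62 to -0.51, -0.46 to -0.13 and -0.29 to -0.17 in light, and from -0.88 to -0.50, -0.57 (without line 2 dark 1, adjusted p = 0.0361) to -0.25 and -1 to -0.81 in dark. Line 1 in dark was not past the threshold without wild type dark 2 (-0.58, adjusted p = 0.0558) or line 1 dark 2 (-0.50, adjusted p = 0.0653).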

Other observations

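Among the neighbouring genes far lower in all 3 labelled lines, chosen after their values were seen, ARP6, an actin-related protein of a chromatin complex, was -3.96 in light and -4.24 in dark, and AT3G33530 beside it on chromosome 3 was -4.50 and -4.82. On chromosome 1 UGT80B1, a sterol glucosyltransferase, was -3.15 and -3.98, and TED6 -5.51 in light (tested probe above background on 3 of 9 line arrays). AT4G06598 and AT4G06599 on chromosome 4 were -4.56 and -4.76 in light and -6.20 and -5.53 in dark. The 3 cytochrome P450 genes CYP705A20, CYP705A21 and CYP705A22 were -3.29, -4.24 and -3.24 in light, with the tested probe above background on 8, 9 and 2 of 9 line arrays.

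Tested line by line with limma, the response to dark differed from the wild type in 281 genes higher and 115 lower in line 1, 647 and 519 in line 2, and 317 and 152 in line 5. Between pairs of lines in light, 146 genes were higher and 129 lower in line 2 than in line 1, and 60 and 35 in line 5 than in line 2. In line 5 against line 1, 0 were higher and 4 lower, with 701 at an unadjusted p under 0.05. In dark the numbers were 39 and 73 for line 2 against 1, 60 and 12 for 5 against 1, and 113 and 93 for 5 against 2.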
